A study of Homo sapiens with 5 samples.

How the data were processed

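The samples were 5 cultures or time points of human cord blood EPCs, with total RNA labelled for a 1-colour Illumina bead array on days 5, 7, 9, 13 and 17. Days 5 and 7 share the label early EPCs and were treated as a group of 2; day 9, day 13 and day 17 each have a label and an array of their own. The deposited table named as not normalized holds a summarised intensity per probe on a linear scale, with no background subtraction and no scaling between arrays. The authors' other table holds log2 values whose minimum and maximum are equal in all 5 columns and whose quartiles and medians differ by less than 0.001, as after quantile normalization; the labels do not state the software. Its columns for days 5, 7, 9 and 17 have a rank correlation of 1 with the intensities of the same day, and its day 13 column has 0.807, so it does not come from the deposited day 13 intensities. Results were computed from the intensities, and those that involve day 13 also from the authors' values.

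The files held no detection p-values, bead numbers, control probes or saturation flags. The background of each array was therefore taken from the intensities below their mode, mirrored around it, which gave a mode of 103 to 112 and an SD of 10.7 to 12.0. A probe was above background at a detection p under 0.01 on that distribution. This differs from the plan made before the data were examined, which named normexp on negative controls or detection p-values. Of 453 probes of olfactory receptor genes, which most cells do not express, 3.75% to 6.84% were above background, so the threshold was looser than its nominal level. Between 35.5% and 39.0% of probes, and between 10629 and 11442 genes, were above background per array. Normexp background correction was fitted to the intensities of each array, an offset of 16 was added, arrays were quantile normalized and values taken to log2 with limma 3.58.1 in R 4.3.3. Plots were made with matplotlib 3.10.9 in Python 3.11.15.

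Of 48803 probes 28098 had 1 gene symbol, 13 had several and 20692 had none; those without 1 symbol were not used. A further 168 probes of Y-linked genes, XIST and genes whose presence depends on a person's haplotype were left out. Each gene was represented by its probe with the highest mean level, and 13442 genes above background on at least 1 array were tested, or 13205 in the authors' table. No genome build was stated with the values, so no positions are given. Identical or closely related genes can share probe signal, which concerns HBG1, HBG2 and HBA2 among the genes named.

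A linear model with stage as a factor of 4 levels was fitted in limma, leaving 1 residual degree of freedom that comes from days 5 and 7, moderated across genes with an intensity trend (prior degrees of freedom 3.73). Tests were two-sided with Benjamini-Hochberg adjustment over all genes at 0.05. The lone arrays were assumed to vary like the early pair, and differences between cultures or donors are not covered. Contrasts were day 17, day 13 and day 9 against the early arrays, day 13 against day 9, and day 17 against day 13. Genes at least 2-fold from both early arrays were counted by size. A gene counted as above background on an array if any of its probes was. Where only 1 of the 2 early arrays was above background, a plain fold from the mean of both is given, and it rests partly on a level near background. A fold against a stage with no array above background was computed against the detection threshold and is given as at least that fold. Fitted differences chose the genes to be named, and a list's median with bounds has such genes at their bound, or at 0 where no bound could be given. Differences within the authors' values were not held to a detection threshold. The number of genes moving one way at every step was compared with all 60 orders of the arrays by an exact permutation test.

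There were 30 gene lists fixed before the data were examined, holding 434 genes of which 388 were measured. They covered endothelial identity, arterial and Notch, venous and lymphatic, VEGF and angiopoietin, adhesion, basement membrane, caveolae, pan-leukocyte, macrophage, MHC class II, T and NK cell, B cell, platelet, erythroid, granulocyte, mesenchymal, stem and progenitor, mitosis, replication, cell cycle inhibitor, lysosome, lipid handling, inflammatory, interferon, glycolysis, cholesterol, TGF-beta, immediate early, ribosomal and housekeeping genes. Each list's median log2 difference was ranked among 10000 random lists of the same size matched on mean expression over all arrays used, in 20 bins. The rule for naming genes, set at the same time, took the 12 largest differences in each direction past the threshold for day 17 against the early arrays, and 5 for each other contrast, or the largest by size where too few passed. It added 9 genes named in any case (PECAM1, CDH5, VWF, KDR, CD34, PROM1, PTPRC, CD14 and MKI67) and up to 4 members per list. PLVAP, ENG, ERG, IL6, PTGS2, COL1A1, PDGFRA, PDGFRB, PRRX1, POSTN, FAP, THY1, CNN1, MYH11, TAGLN and COL6A3 are named beyond that rule and were chosen after their values were seen. The authors' day 13 value of LUM was also chosen in that way.

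The procedure was tested on simulated data with known changes. Each gene's noise was drawn from the spread fitted by the model, equal on all 5 arrays and without donor, culture or array effects. The simulation therefore does not test whether a lone array varies like the early pair. With 200 changed genes it recovered 9.88% of genes changed 4-fold, 45.1% at 8-fold and 97% at 64-fold on day 17, with 8.26% of calls false, above the nominal 5%. With 3000 changed genes it recovered 79.7% at 4-fold, with 4.55% of calls false. Alternatives planned before the data were examined were median scaling, no background correction, an offset of 50, the authors' values, no detection filter, detection on at least 2 arrays, a detection p of 0.05, the mean of a gene's probes, no intensity trend, a straight line over days, other size limits, unmatched random lists and leaving out each early array. Leaving out the day 13 array was added after seeing the data.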

Results

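Total RNA from endothelial progenitor cells (EPCs) grown out of human umbilical cord blood was measured on 5 Illumina bead arrays, with 1 array each on days 5, 7, 9, 13 and 17 of a culture under endothelial differentiation conditions. The labels name the cells of days 5 and 7 early EPCs (n = 2), those of day 9 as starting to differentiate, those of day 13 as partly differentiated and those of day 17 as OECs, the fully differentiated stage. OEC is the field's usual name for outgrowth endothelial cells, an adherent and proliferating endothelial culture. Early EPC cultures are known from textbooks to hold many cells with monocyte and macrophage features, so markers of blood cells were followed beside endothelial ones. Median probe intensities lay between 113 and 123, and between 17336 and 19044 of the 48803 probes of each array stood above the background estimated from that array. The analysis covered 13442 genes. The number of arrays limits the precision: every stage after day 7 had 1 array, and each SE and p-value rests on the spread between the 2 early arrays, which were taken 2 days apart. The labels do not say whether the arrays share a donor or a culture.

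The first comparison asked which transcripts set the day 17 OECs apart from the early EPCs. The day 17 culture carried high levels of endothelial, caveolar and matrix transcripts that were near or below background on days 5 and 7, and most macrophage markers, among the brightest transcripts on those days, were at or near background. CDH5, the VE-cadherin of endothelial junctions, rose by 8.18 on the log2 scale (SE 0.45, adjusted p = 0.00163), a 289-fold difference. VWF, the clotting factor carrier stored in endothelial granules, rose 132-fold. TYROBP, a signalling adaptor of myeloid cells, fell by 10.85 on the log2 scale (SE 0.22, adjusted p = 0.000525) to a level not above background, at least 734-fold lower. CD14, the lipopolysaccharide co-receptor of monocytes, fell 164-fold and was still above background on day 17. In the limma test 1495 genes rose and 1250 fell, and 4727 genes had an unadjusted p under 0.05 where 672 would be expected by chance. Among genes with a size of at least 2-fold from day 5 and from day 7 alike, 1976 were higher and 1753 lower. The share of higher genes among those passing the test was 54.5%, and it was 65.2% when arrays were scaled to the same median in place of quantile normalization, a choice that moved the median of all genes by 0.23. A straight line fitted over the days in limma, which asks for a steady change, passed 0 genes, with 2159 at an unadjusted p under 0.05 and a smallest adjusted p of 0.310.

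The 12 largest fitted increases included genes of the extracellular matrix, the caveolae and the vessel wall. EFEMP1, a fibulin of elastic matrix, rose by 9.01 (SE 0.77), and SULF1, an extracellular heparan sulfatase, by 8.91 (SE 0.69). TM4SF1, a membrane protein abundant on endothelial cells, rose by 8.78, BGN, the proteoglycan biglycan, by 8.70, and CAV1, the main caveolar coat protein, by 8.68. The matricellular genes CCN1 and CCN2 rose, CCN1 at least 201-fold from arrays where it was not above background and CCN2 277-fold. SOX18, an endothelial transcription factor, rose at least 251-fold. MGP, an inhibitor of calcification, rose 312-fold, EDN1, the vasoconstrictor endothelin-1, 270-fold, and COL5A2, a chain of fibrillar collagen, at least 221-fold. Of these 12 genes, CCN2 was above background on both early arrays, CCN1, SOX18 and COL5A2 on neither, and the others on 1 of them, which leaves their order by size uncertain. EFEMP1 and BGN, at 15.95 and 15.90 on day 17, were near the top of the intensity scale.

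The endothelial identity list, fixed before the data were examined, had a median difference of 4.76, or 4.63 with genes not above background held at their bounds. Of its 24 measured genes 20 rose, 0 fell and 4 did not pass, while adjusted over the list alone 21 rose and 1 fell. CLEC14A, an endothelial lectin, rose 211-fold, and KDR, the main VEGF receptor, rose at least 3.99-fold (adjusted p = 0.0148). PECAM1, the platelet and endothelial adhesion molecule CD31, was already bright on days 5 to 13, and its difference of 1.11 (SE 0.28) did not pass with an adjusted p of 0.0538, although it passed under median scaling with 0.0302. The others that did not pass were ENG at 0.90, ERG at -1.79 and PLVAP, not above background on the early arrays, at least 1.02-fold higher. All 8 caveolar genes were measured and 7 rose, with the same 7 adjusted over the list alone and a median of 5.69, and among them CAVIN1 rose 190-fold. In the VEGF and angiopoietin list 9 of 16 rose and 1 fell (11 and 1 adjusted over the list alone, median 3.03). ESM1, a proteoglycan of endothelial tip cells, rose at least 70.1-fold and ANGPT2, a ligand of the TEK receptor, at least 19.9-fold. In the arterial and Notch list 6 of 14 rose and 2 fell (7 and 2 adjusted over the list alone, median 1.18, or 0.53 and within the random lists when genes had to be above background on 2 arrays). EFNB2, an arterial ephrin, rose 41.2-fold, JAG2, a Notch ligand, rose 13.5-fold, and CXCR4, a chemokine receptor of leukocytes and endothelial tip cells, fell by 3.68 on the log2 scale. In the venous and lymphatic list 2 of 8 rose and 1 fell (4 and 1 adjusted over the list alone, median 0.31, or -0.60 under that filter). EPHB4, the venous receptor of EFNB2, rose 38.4-fold, and PDPN, a glycoprotein of lymphatic endothelium and some macrophages, fell at least 23.3-fold. In the adhesion and leukocyte recruitment list 3 of 10 rose and 1 fell (5 and 1 adjusted over the list alone, median 1.46). JAM3, a junctional adhesion molecule, rose 41.2-fold, while VCAM1, an adhesion receptor for leukocytes, had a difference of 4.68 that did not pass, with a level of 5.61 on day 5 and 9.72 on day 7.

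Matrix genes rose beside the endothelial ones. Of 18 measured basement membrane and matrix genes 14 rose and 0 fell (15 and 0 adjusted over the list alone), with a median of 4.19. COL4A1, a collagen of basement membranes, rose 190-fold and the laminin chain LAMB1 at least 59.4-fold. In the list of fibroblast, mesenchymal and smooth muscle markers 5 of 8 rose and 0 fell (5 and 0 adjusted over the list alone, median 2.5), led by COL3A1, a fibrillar collagen, at least 73.0-fold. The median was 0.32 with no detection filter and 0.27 over the 13 genes tested in the authors' values, within the random lists in both, and 2.22 in the authors' values over the same 8 genes. COL1A1, PDGFRB, PRRX1, POSTN, FAP, THY1, CNN1 and MYH11 of that list were not above background on day 17. In the TGF-beta list 5 of 13 rose and 3 fell (5 and 3 adjusted over the list alone, median 0.94). Without the day 7 array its median was 0.42, within the random lists. CDH2, the N-cadherin of mesenchymal and endothelial cells, rose 88.6-fold, while S100A4, a calcium-binding protein also abundant in macrophages, fell by 8.64 on the log2 scale.

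**Figure D1:**
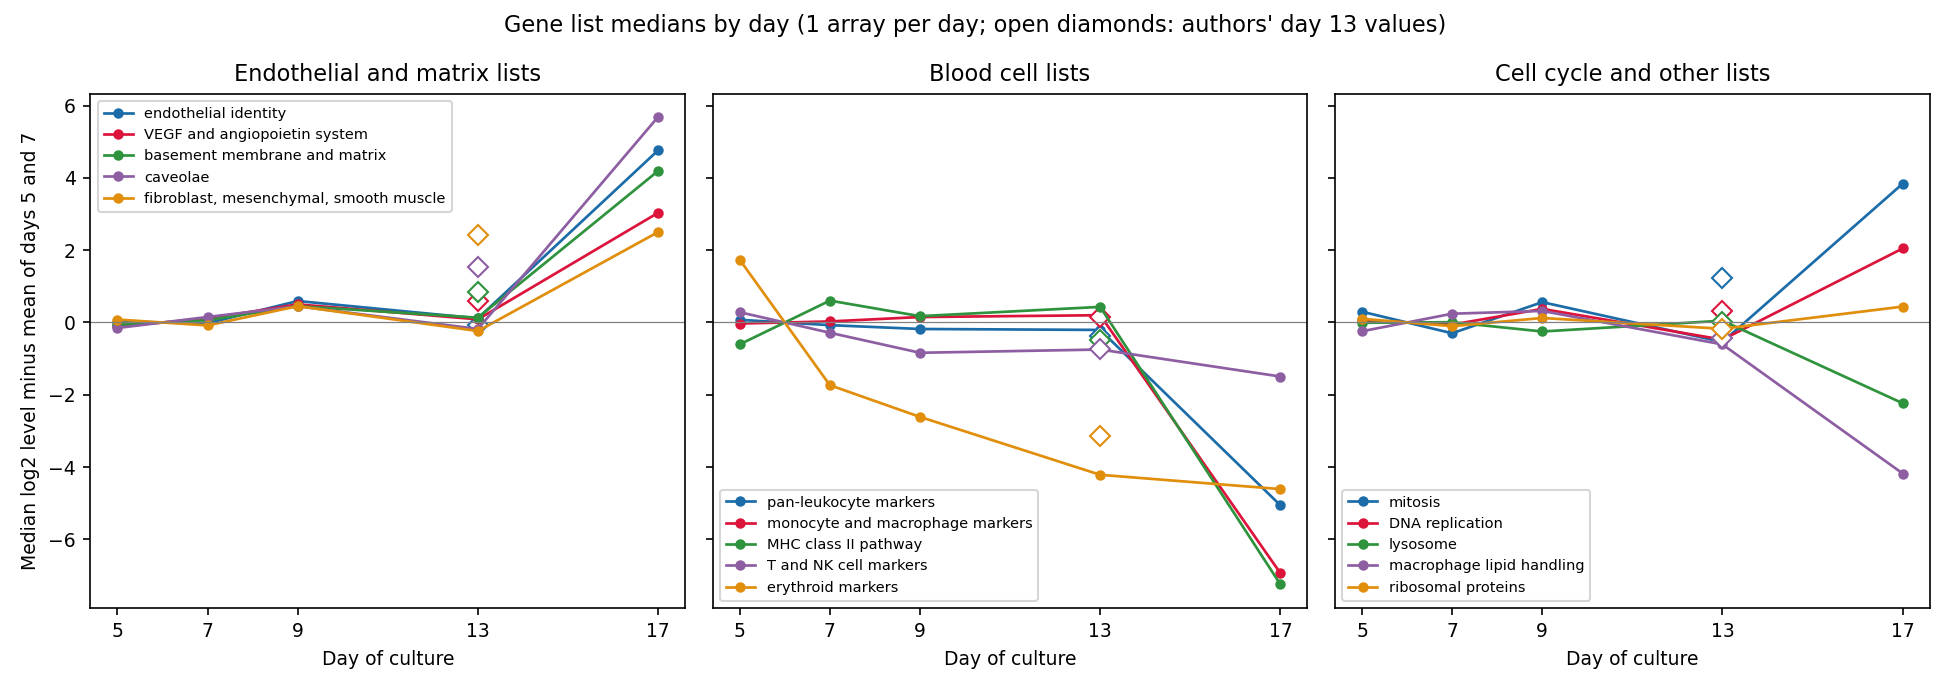
Median log2 level of the genes of 15 lists on each day of culture, minus the mean of days 5 and 7, with 1 array per day and open diamonds for the authors' day 13 values. The endothelial identity list lay at 0.59 on day 9, 0.11 on day 13 and 4.76 on day 17, the monocyte and macrophage list at -6.93 on day 17, and the mesenchymal list at -0.24 on day 13 over 8 genes from the intensities and 2.42 over 13 genes from the authors' values.

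Most blood cell lists were lower on day 17 than on the early arrays. The B cell, platelet and erythroid lists also had medians below 0 on day 13, of -1.64, -1.16 and -4.21 (-1.32, -0.63 and -3.70 with bounds, and -0.95, -0.55 and -3.15 with the authors' values), with 4 of 7, 0 of 9 and 0 of 8 genes lower adjusted over the list alone and 0 over all genes. The T and NK cell, granulocyte and pan-leukocyte medians on day 13 were -0.75, -0.39 and -0.21 (-0.74, -0.59 and -0.37 with the authors' values). Of their genes 2, 2 and 0 were lower adjusted over the list alone. The macrophage and MHC class II medians were 0.20 and 0.43 (0.14 and -0.48 with the authors' values). Between days 13 and 17, 5, 7 and 8 genes of the B cell, platelet and erythroid lists gave only a bound, so a further fall could hardly be seen. Of 24 monocyte and macrophage markers 21 fell and 0 rose (22 and 0 adjusted over the list alone), with a median of -6.93. The complement genes C1QB and C1QC fell at least 678-fold and at least 720-fold, CSF1R, the receptor of macrophage colony-stimulating factor, at least 508-fold, and CD163, the macrophage scavenger receptor of haemoglobin, at least 701-fold. PLA2G7, a macrophage phospholipase, ADAMDEC1, a protease of macrophages and dendritic cells, and S100A9, a calcium-binding protein of myeloid cells, fell at least 408-fold, 362-fold and 471-fold, and LYZ, lysozyme, by 9.31 on the log2 scale. Of 8 genes of the MHC class II pathway 7 fell (8 adjusted over the list alone, median -7.24), among them HLA-DRA at least 738-fold, HLA-DMB at least 586-fold and the invariant chain CD74 at least 402-fold. Of 17 pan-leukocyte markers 15 fell (15 adjusted over the list alone, median -5.06), with PTPRC, the leukocyte phosphatase CD45, at least 17.7-fold lower and LCP1, an actin bundling protein, at least 431-fold lower. Of 13 granulocyte and mast cell markers 6 fell (7 adjusted over the list alone, median -3.47), and the granule enzymes MPO and ELANE fell at least 97.7-fold and at least 56.2-fold. In the T and NK cell list 6 of 14 fell (8 adjusted over the list alone, median -1.49), in the B cell list 3 of 7 (3 adjusted over the list alone, median -1.68), and in the platelet list 1 of 9 (1 adjusted over the list alone, median -1.17). With the authors' values these medians were -0.86, -1.02 and -0.56, with 4, 3 and 0 genes lower, and over the alternatives they ranged from -0.86 to -2.34, -1.02 to -2.30 and -0.56 to -1.77. That platelet gene, GP9, and the NK cell granule gene NKG7 no longer passed without background correction, with adjusted p of 0.0681 and 0.0611. The 8 erythroid genes had a median of -4.61, or -0.73 with no detection filter, but 0 passed in limma, over all genes or adjusted over the list alone, and HBB, a haemoglobin chain, was at 13.79 on day 5 and 9.10 on day 7. With genes not above background held at their bounds, the granulocyte, B cell, platelet and erythroid medians were -2.93, -1.22, -0.53 and -3.84. Many macrophage probes were near the top of the intensity scale on days 5 to 13, where the brightest probe of each array reached 65834 to 67794, which limits the differences that can be read for them.

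Lysosomal and lipid handling genes fell, as the macrophage markers did. Of 14 lysosomal genes 13 fell (13 adjusted over the list alone, median -2.23), with CTSD, the protease cathepsin D, 23.2-fold lower and LIPA, the acid lipase, 16.8-fold lower. Of 13 genes of macrophage lipid handling 8 fell (10 adjusted over the list alone, median -4.18, or -3.33 with bounds), with APOE, an apolipoprotein, 604-fold lower and CD36, a fatty acid receptor, 248-fold lower. In the list of inflammatory cytokines and NF-kB targets 6 of 14 fell and 2 rose (7 and 2 adjusted over the list alone, median -1.67, or -1.21 with bounds and -0.99 with the authors' values). IL1B and TNF, cytokines of activated macrophages, fell at least 8.37-fold and 7.36-fold, while IL6, a cytokine of many cell types, rose by 2.57 and PTGS2, a prostaglandin synthase, by 3.08.

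Cell cycle genes rose on day 17. All 16 mitosis genes rose (16 adjusted over the list alone) with a median of 3.84, including CDC20, an activator of mitotic exit, 41.3-fold and BIRC5, survivin, 33.4-fold. MKI67, the Ki-67 antigen of dividing cells, rose at least 4.16-fold (adjusted p = 0.0428) but had an adjusted p of 0.0524 when genes had to be above background on 2 arrays. Of 16 DNA replication genes 12 rose (15 adjusted over the list alone, median 2.05), with TYMS, thymidylate synthase, 18.1-fold higher. In the list of cell cycle inhibitors and senescence genes 4 of 10 rose and 0 fell (5 and 0 adjusted over the list alone, median 0.79, or 0.15 with bounds). These were IGFBP7, a secreted vascular protein, GDF15, a stress cytokine, GADD45A, a DNA damage gene, and CDKN1A, the p21 inhibitor, which rose by 4.95, 3.54, 2.42 and 1.94.

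Stem cell markers went both ways. In the list of haematopoietic stem and progenitor markers 1 of 11 rose and 3 fell (5 and 3 adjusted over the list alone, median 0.06). CD34, shared by progenitors and endothelium, rose by 4.18 with its brightest probe, while its 3 probes ranged from 0.20 to 4.18, and MYB, a transcription factor of blood progenitors, fell by 4.0. PROM1, the CD133 antigen often used to select EPCs, had a difference of 0.06 (SE 0.37, adjusted p = 0.934). In the glycolysis list 3 of 13 rose and 0 fell (6 and 2 adjusted over the list alone, median 0.76), including PFKP, a phosphofructokinase, 25.6-fold. The glycolysis median was 0.39 with detection on 2 arrays and 0.49 without the day 5 array, within the random lists in both. In the cholesterol synthesis list 2 of 9 rose and 0 fell (2 and 1 adjusted over the list alone, median -0.37, or 0.04 without the day 7 array), in the interferon list 2 of 14 rose and 1 fell (2 and 3 adjusted over the list alone, median -0.10), and in the immediate early and heat shock list 0 of 11 rose and 3 fell (0 and 3 adjusted over the list alone), with a median of 0.29 (-0.16 without the day 5 array) and a mean of -0.49. Of 16 ribosomal protein genes 0 passed in limma, over all genes or adjusted over the list alone, with a median of 0.44, although RPL13, a large subunit protein, with a difference of 0.93 and an adjusted p of 0.0993, passed under median scaling (adjusted p = 0.0465) and with the mean of its probes (adjusted p = 0.0161). Of 12 housekeeping genes 1 rose and 2 fell (2 and 2 adjusted over the list alone, median -0.02): GAPDH, a glycolytic enzyme, rose by 1.48, and B2M, the light chain of MHC class I, and GUSB, a lysosomal enzyme, fell by 1.27 and 1.77. Under median scaling the interferon and housekeeping medians turned sign, to 0.24 and 0.10, as they did without the day 5 array, to 0.20 and 0.06, and HSPA1A, a heat shock protein that fell by 1.79, no longer passed (adjusted p = 0.0573).

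**Figure D2:**
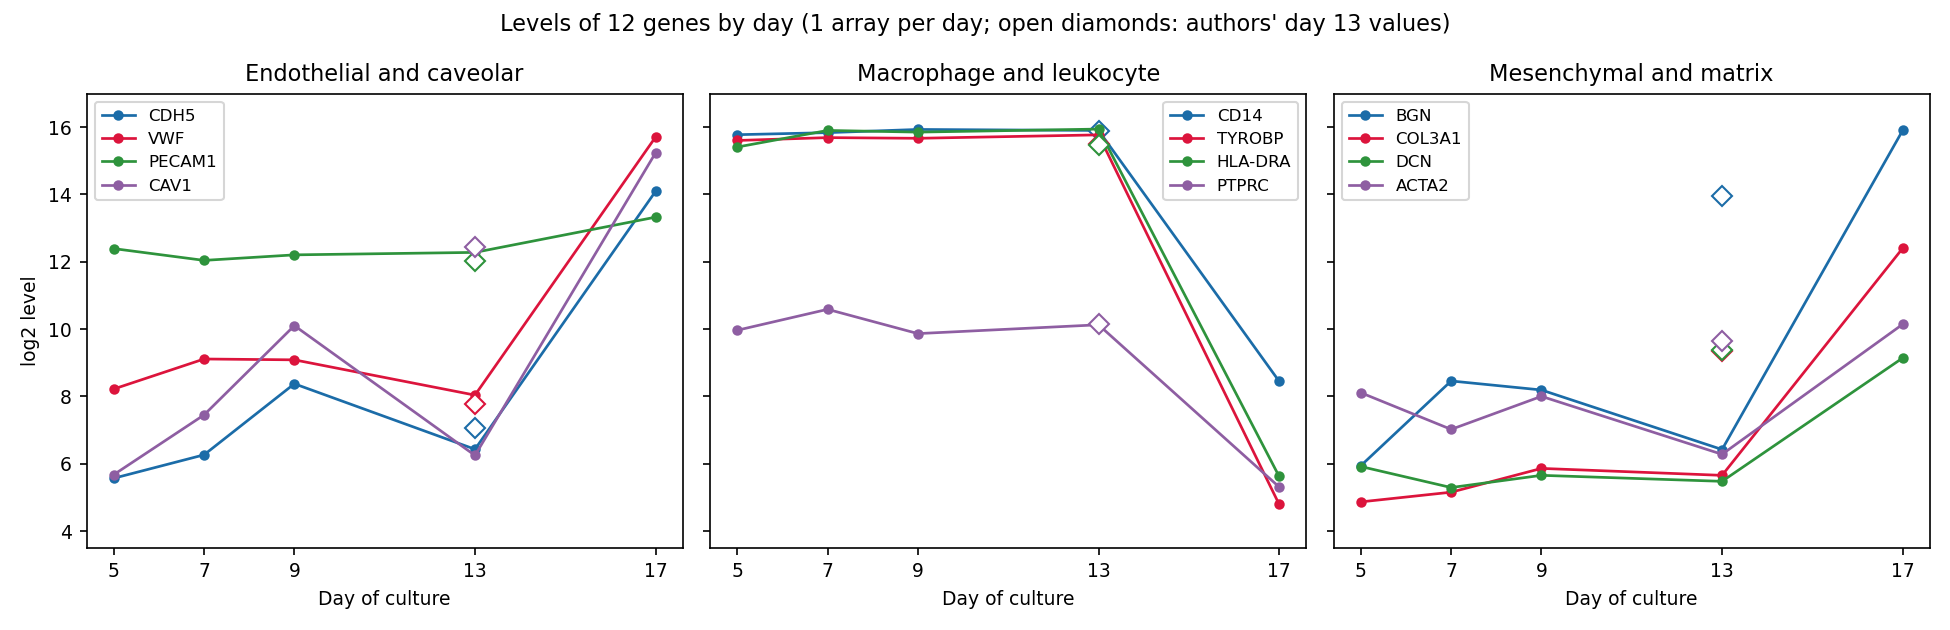
Log2 levels of 12 genes on each day of culture, 1 array per day, with open diamonds for the authors' day 13 values, which are on the authors' own normalized scale. CDH5 lay at 8.38 on day 9, 6.43 on day 13 and 14.09 on day 17, CD14 between 15.78 and 15.93 on days 5 to 13 and at 8.45 on day 17, and BGN on day 13 at 6.42 from the intensities and 13.95 in the authors' values.

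The comparison of day 17 with day 13 asked what separated the last 2 stages. Most endothelial lists were again higher, and macrophage lists lower, on day 17. The arterial and adhesion lists had medians of 0.86 and 1.64, or 0.15, within the random lists, and 0.58 with the authors' values. The venous and lymphatic list had a median of -0.18 (0.18 with bounds and 0.46 with the authors' values), with 2 of 8 genes higher and 1 lower (3 and 1 adjusted over the list alone). From the day 13 intensities, EFEMP1 rose at least 823-fold, MYH10, a non-muscle myosin, at least 287-fold, FHL2, a cytoskeletal adaptor, at least 336-fold, and SULF1 at least 296-fold. These bounds do not rest on the authors' day 13 column. TYROBP, ADAMDEC1, C1QB, C1QC and HLA-DRA fell at least 799-fold, 745-fold, 771-fold, 837-fold and 901-fold. The endothelial identity list had a median of 4.75 with 20 of 24 genes higher and 0 lower (21 and 1 adjusted over the list alone), and the monocyte and macrophage list a median of -7.28 with 20 of 24 lower and 0 higher (22 and 0 adjusted over the list alone). Of 16 mitosis genes 14 rose (16 adjusted over the list alone). These list values are from the intensities, where the mitosis median lay at -0.54 on day 13 and 3.84 on day 17 relative to the early arrays. With the authors' values it lay at 1.24 and 3.24, the endothelial identity median at -0.07 and 3.95, and the monocyte and macrophage median at 0.14 and -5.76. From the intensities 1176 genes rose and 1019 fell in limma, a share of 53.6% higher that became 67.6% under median scaling, with a shift of 0.34 in the median of all genes. With the authors' day 13 values 897 rose and 773 fell. BGN rose by 9.48 (SE 1.22, adjusted p = 0.0111) from the intensities, but by the authors' values its difference was 1.99 and did not pass (adjusted p = 0.206). The mesenchymal list had a median of 2.94 with 5 of 8 genes higher and 0 lower (7 and 0 adjusted over the list alone) from the intensities, and -0.58 with 1 of 13 higher and 5 lower (2 and 6 adjusted over the list alone) from the authors' values, which had a median of 0.19 over the same 8 genes.

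At day 9, named by the labels as the start of differentiation, the array still resembled the early EPCs, with some endothelial transcripts above them. The endothelial identity list had a median of 0.59 against the early arrays, or 0.38 with bounds and 0.29 with the authors' values. It was higher than all random lists, but those were matched on the mean of all 5 arrays, day 17 included, and not on the early level. Other lists also lay outside the random lists. The mitosis list was higher than all of them, the monocyte and macrophage list, with a median of 0.15, higher than 98.8%, and the lysosome list higher than only 0.18%. CDH5 stood at 8.38 on day 9 against 5.57 and 6.26 on days 5 and 7, and CAV1 at 10.10 against 5.67 and 7.45. The 5 genes with the highest fitted differences were TM4SF1 with 4.04, LYVE1, a hyaluronan receptor of lymphatic endothelium and some macrophages, with 3.78 but at 13.23 against 11.46 and 7.44 on days 5 and 7, CAV1 with 3.54, and GLDN, a secreted adhesion protein, and CGNL1, a junctional protein, which were not above background on the early arrays and were at least 10.1-fold and 7.39-fold higher. The lowest were the haemoglobin genes HBB at -5.16, HBA2 at -5.03, HBG2 at -4.34 and HBG1 at -4.21, and MMP25, a leukocyte metalloprotease, at -3.86. The 4 haemoglobin genes were at 6.29, 7.02, 7.61 and 7.46 on day 9, at 9.10, 9.42, 9.18 and 8.85 on day 7 and at 13.79, 14.67, 14.70 and 14.49 on day 5. Probes of HBG1 and HBG2, or of other paralogs of the haemoglobins, can read each other's transcripts. In limma 0 genes passed, with 462 at an unadjusted p under 0.05 where 672 would be expected by chance. Adjusted over the list alone, and not corrected across lists, 2 endothelial identity genes, 4 basement membrane genes, 3 caveolar genes, 2 genes of the VEGF list, 3 granulocyte genes, 2 genes of macrophage lipid handling, 1 mesenchymal gene and 1 cell cycle inhibitor gene were higher, and 4 B cell genes, 2 T and NK cell genes and 1 granulocyte gene were lower. With the authors' day 9 values these counts were 0, 3, 3, 0, 3, 2, 1 and 1 higher and 3, 2 and 1 lower. The erythroid list had a median of -2.61, the B cell list -1.85 and the mitosis list 0.56, or -2.14, -0.87 and 0.38 with the authors' values. At least 2-fold from both early arrays were 180 genes higher and 105 lower, and the authors' values gave 79 and 38. In simulated data with equal noise on all 5 arrays, the same test recovered 9.13% of genes changed 4-fold when 200 genes changed. For genes changed 16-fold it recovered 82.1%.

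Day 13 had different values in the 2 deposited tables. The authors' day 13 column had a rank correlation of 0.807 with the day 13 intensities, while on the other 4 days the 2 tables had a rank correlation of 1. Day 13 counts and list medians were therefore computed from both. Single genes are given from the intensities unless the authors' values are named. From the intensities, day 13 was close to the early arrays in its endothelial genes, with a median of 0.11 for the identity list, 0.13 for basement membrane and -0.18 for caveolae. The haematopoietic stem and progenitor list had a median of -1.53, or -1.03 with bounds, with 7 of 11 genes lower adjusted over the list alone (-0.88 and 6 of 11 with the authors' values), and the mitosis list had -0.54. By size in the day 13 intensities the highest genes were RETN, the myeloid cytokine resistin, with 4.85 but at 12.79 against 9.67 and 6.20 on days 5 and 7, HTRA1, a secreted protease, with 4.36, RAD51B, a DNA repair gene, 11.3-fold higher, ATP6V0D2, a proton pump subunit of macrophages and osteoclasts, with 3.47, and KLF4, a transcription factor of monocytes and endothelium, with 3.35. The lowest were HBG2, HBA2, HBG1 and HBB, at least 51.3-fold, 55.1-fold, 42.4-fold and 36.3-fold lower than the mean of early arrays that differed as above, and SEPTIN5, a septin of platelets and neurons, at least 17.3-fold lower. Bounds of this kind rest on the day 13 intensities and not on the authors' day 13 column. In limma 0 genes passed, with 616 at an unadjusted p under 0.05. At least 2-fold from both early arrays were 170 genes higher and 208 lower.

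From the authors' day 13 values, mesenchymal and matrix transcripts were high. The fibroblast, mesenchymal and smooth muscle list had a median of 2.42, with 3 of 13 genes higher over all genes and 11 adjusted over the list alone. COL1A1, the main collagen of connective tissue, was at 12.49 against a mean of 7.00 on the authors' early arrays, and TAGLN, a smooth muscle actin-binding protein, was at 12.48, 7.69-fold higher. The mitosis list had a median of 1.24 (11 of 16 higher adjusted over the list alone, 0 over all genes), caveolae 1.55 (4 of 8 and 0) and basement membrane 0.83 (8 of 18 and 1), while the endothelial identity list had -0.07 (0 of 24 and 0) and the macrophage list 0.14. In limma 33 genes rose and 0 fell, with a smallest adjusted p of 0.0484 and 1079 genes at an unadjusted p under 0.05. COL6A3, a chain of collagen VI, had the largest difference among those of the 33 that were also tested from the intensities, 6.08. RETN turned direction, at -0.60 by the authors' values. At least 2-fold from both early arrays were 375 genes higher and 104 lower.

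**Figure D3:**
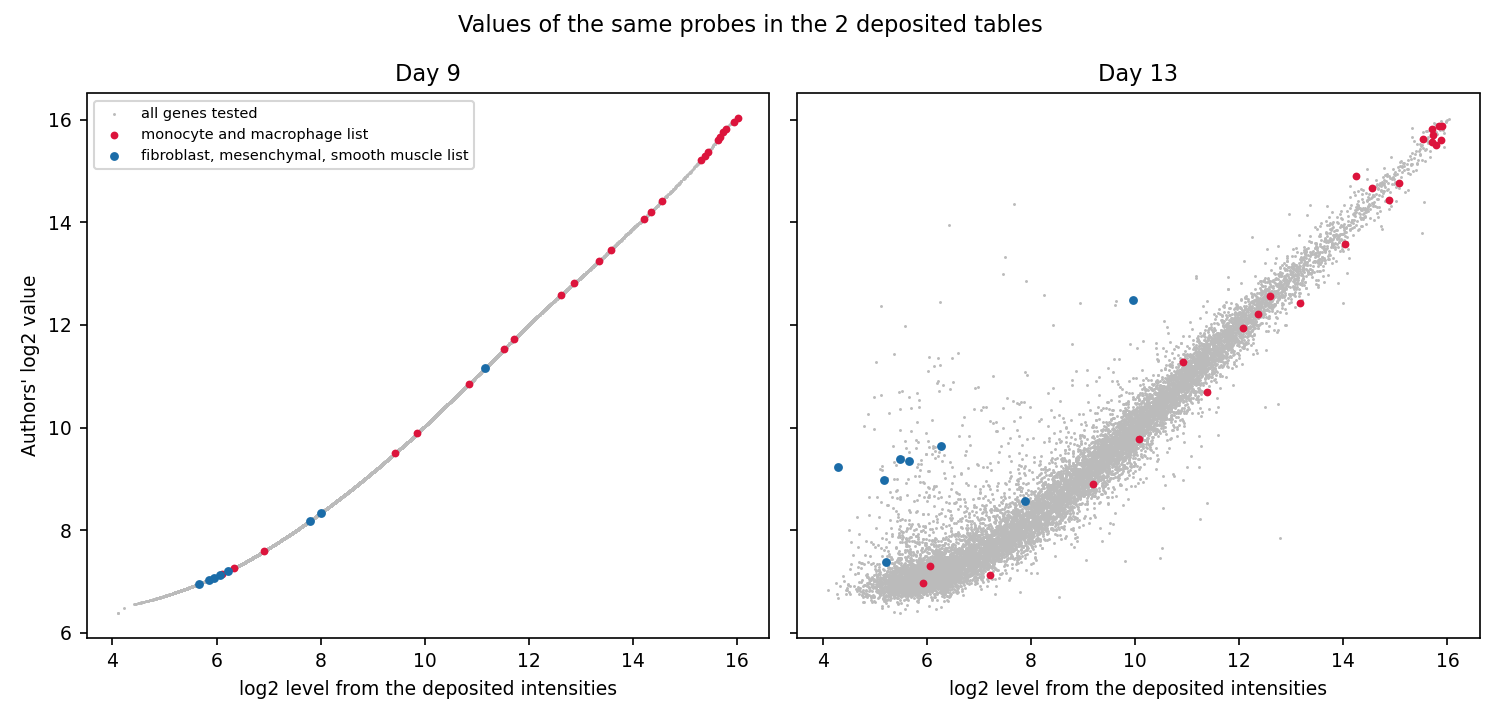
Authors' log2 values against log2 levels from the deposited intensities for the same probes on day 9 and on day 13, with each grey point a gene, red points the monocyte and macrophage list and blue points the mesenchymal list. On day 9 the ranks were identical (rank correlation 1), and on day 13 the rank correlation was 0.807 with mesenchymal genes such as ACTA2 at 9.64 in the authors' column and 6.28 from the intensities.

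Against day 9, day 13 from the intensities had lower medians in some endothelial lists and in the cell cycle lists. The endothelial identity list had a median of -0.66, caveolae -1.06, mitosis -1.12 and macrophage lipid handling -1.48 (-0.41, -0.66, -1.06 and -1.48 with bounds), and adjusted over the list alone 1, 3, 4 and 4 of their genes were lower, against 0, 0, 0 and 2 with the authors' values, where 4 caveolar genes were higher. The arterial, adhesion and venous lists had -0.16, -0.02 and 0.11, within the random lists. The 5 genes with the highest fitted differences were OLFML3, a secreted matrix protein, 18.4-fold higher, ITGB7, an integrin of leukocytes, with 3.98, and UTS2, the vasoactive peptide urotensin 2, YPEL4 and SIGLEC12, a sialic acid binding lectin, which were not above background on day 9 and were at least 19.1-fold, 12.8-fold and 8.66-fold higher. Those with the lowest were SEL1L3 at -4.84, LYVE1 at -4.57, PPARG, a lipid-sensing nuclear receptor of macrophages, at -4.16, CCL24, a chemokine of macrophages, at -4.14, and SEPTIN5, not above background in the day 13 intensities, at least 17.5-fold lower. All these gene values rest on the day 13 intensities and not on the authors' day 13 column. In limma 0 genes passed, with 670 at an unadjusted p under 0.05. With the authors' values 0 passed, with 1029 at an unadjusted p under 0.05, and the mitosis and caveolae medians were 0.92 and 0.85, opposite in sign. So were basement membrane (-0.39 with 2 genes lower adjusted over the list alone, against 0.64 with 6 higher and 1 lower), VEGF (-0.57 against 0.10), replication (-0.59 against 0.10), cell cycle inhibitors (-0.44 against 0.18) and the mesenchymal list (-0.81 over 8 genes against 1.90 over 13), and MHC class II (0.30 against -0.62) and interferon (0.17 against -0.24) the other way.

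The 2 early arrays also differed. Day 7 was at least 2-fold higher than day 5 in 543 genes and lower in 603, without a test since each day had 1 array. The erythroid list had a median of -3.47 on day 7 against day 5, platelet markers -1.54, granulocyte markers -0.96, B cell markers -0.79, mitosis -0.59 and interferon-stimulated genes -0.56. The MHC class II list was 1.21 higher, inflammatory cytokines 0.98 and cholesterol synthesis 0.95. HBA2, a haemoglobin chain, was at 14.67 on day 5 and 9.42 on day 7, and CCL3, a macrophage chemokine, at 9.48 and 13.38. The authors' values gave 598 genes at least 2-fold apart in place of 1146.

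Whether genes moved steadily over the days was tested by the order of the arrays. From day 5 to day 17, 107 genes rose and 104 fell at every step by at least 2-fold in all. Of the 60 possible orders of the 5 arrays, 20 gave as many or more (exact permutation p = 0.333, one-sided, smallest possible p = 0.0167), and the highest count in another order was 368. With the authors' values the count was 336 and 4 of 60 orders gave as many (exact permutation p = 0.0667), or 197 and 2 of 60 for changes of at least 4-fold (exact permutation p = 0.0333). Across genes, which are not independent replicates, the arrays of days 5 to 13 had correlations of 0.964 to 0.976 with each other and 0.720 to 0.744 with day 17. In each of the counts above, the highest other order also ended with day 17. The order test thus weighs the distance of day 17 as well, and does not test the order of the earlier days alone.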

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

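All tests of explanations given here were chosen after the values were seen. The authors' day 13 column stood out because it holds a signal that the deposited day 13 intensities lack. Its rank correlation with those intensities was 0.807, and its fibroblast, mesenchymal and smooth muscle list stood 2.42 above the authors' early arrays on the log2 scale over 13 genes; over the 8 genes measured in both tables it stood 2.25 above, against -0.24 from the intensities, where 5 of the 8 gave only a bound.

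Normalization by the authors or a mix-up among the 5 arrays is argued against by the ranks, since the highest rank correlation of the column with any of the 5 intensity columns was 0.816, for day 9, while each other column reached 1 with its own day. A blend of the day 13 and day 17 RNA is argued against by 4 mesenchymal genes, COL1A1, PRRX1, PDGFRB and POSTN, which were below background in both of those arrays and 5.49, 3.96, 3.20 and 2.42 above the early arrays in the column. RNA of mesenchymal cells is a candidate explanation. The list median of 2.42 is the flagged observation itself and no separate support. COL1A1 was at 12.49, TAGLN at 12.48, and COL1A2 and COL3A1 at 8.98 and 9.35 against 6.90 and 6.72 on the early arrays. MYH11 and CNN1 of the same list were at 6.81 and 6.88 against 6.82 and 6.74. LUM, PDGFRA and THY1, also of that list, were only 1.33-fold, 1.45-fold and 1.91-fold higher. In addition, 5 of the list's genes also rose in the day 17 culture. Over 13033 genes the column had a Pearson correlation of 0.970 with the day 13 intensities, above its 0.953, 0.953, 0.960 and 0.789 with days 5, 7, 9 and 17. Which sample the column came from, and whether a day 13 culture differed in its cells, was not tested and stays open.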

How the results depend on the processing

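Leaving out the day 13 array was chosen after seeing the data; the other alternatives were planned. The count of genes past the limma test for day 17 against the early arrays, 2745, lay between 2270 and 3077 under 9 changes of processing and was 2482 without an intensity trend, and the genes shared with it, 2269 to 2734, all kept their direction. Genes that pass in 2 fits of the same arrays could hardly change direction. The count became 0 with a straight line over the days, which tests a steady change and not day 17 alone, with 2159 genes at an unadjusted p under 0.05. For day 17 against day 13 the count of 2195 lay between 1670 and 2584. For day 13 against the early arrays, 33 genes passed with the authors' values and 0 in limma under the 8 other alternatives run for it; for day 9 against the early arrays and day 13 against day 9 it was 0 under the 10 and 9 run, with 462 and 670 genes at an unadjusted p under 0.05 by the chosen processing. Counts by size moved more; except for the stricter size limit, the cause was not tested. From 285 genes at day 9, 378 at day 13 and 1146 between days 5 and 7, counts became 136, 183 and 671 without background correction, and 166 and 221 at days 9 and 13 with an offset of 50. With the authors' values they were 117 at day 9 and 598 between days 5 and 7. At 4-fold in place of 2-fold they were 26, 57 and 180, and 1763 in place of 3729 at day 17. Genes moving one way over all days, 211, became 109 at 4-fold, 336 with the authors' values and 989 over 4 days without the day 13 array (exact permutation p = 0.25), where fewer steps are asked for. Leaving out each early array, a setting with no test since no residual degree of freedom is left, gave 826 to 1031 genes at day 9, 1059 to 1130 at day 13 and 821 to 1068 moving one way, since 1 early array has to be passed in place of 2. RETN at day 13 against the early arrays reversed to -0.60 with the authors' values; the cause was not tested. Among named genes in the day 17 contrasts, 1595 values were unchanged, 13 no longer passed, 8 newly passed and 5 moved with an early array left out. Unchanged means on the same side of the threshold or, with an early array left out and no test, within the SD of the 2 early arrays. The mean of the early arrays moves by less than that SD when 1 is left out, so the second criterion could hardly fail. Of 330 list medians for day 17 against the early arrays, 238 moved by less than the spread between the early arrays, 92 by more, and none past its limits reversed; 22 to 24 of the 30 lists lay outside the random lists in each setting. Lists that came to lie within them were the mesenchymal list, from a median of 2.5 to 0.27 with the authors' values, where 13 genes were tested in place of 8, and 0.32 with no detection filter; the arterial and glycolysis lists, at 0.53 and 0.39 with detection on 2 arrays; the cell cycle inhibitor list, at 0.35 to 0.92 in 5 changes of processing; and the glycolysis, cell cycle inhibitor, TGF-beta and ribosomal lists, at 0.49, 0.68, 0.42 and 0.35 with one early array left out, where the venous and cholesterol lists came to lie outside, at 1.27 and -1.14. With no detection filter the erythroid median went from -4.61 to -0.73 and stayed outside. The T and NK cell, B cell, inflammatory and arterial medians became -0.86, -1.02, -0.99 and 0.76 with the authors' values and stayed outside. Among lists within the random lists, medians near 0 turned sign: immediate early, interferon and housekeeping to -0.16, 0.20 and 0.06 without the day 5 array, cholesterol to 0.04 without the day 7 array, interferon and housekeeping to 0.24 and 0.10 under median scaling, and the venous list to -0.60 with detection on 2 arrays. Signal over background limits the genes near the threshold, whose differences are bounds. No paired analysis was possible because the labels give 1 array per day and do not say which arrays share a donor or a culture.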

Other observations

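Neutrophil granule genes were bright through the first 4 days measured. MPO, the peroxidase of neutrophil granules, was at 12.60, 12.87, 13.73 and 11.63 on days 5, 7, 9 and 13, ELANE, neutrophil elastase, at 11.98, 11.90, 13.45 and 11.86, and AZU1, azurocidin, at 10.20, 9.93, 11.61 and 10.69, and none of these was above background on day 17. OAS1, an interferon-induced antiviral enzyme, was highest on day 9, at 12.12, against 10.15, 10.69, 10.60 and 8.53 on days 5, 7, 13 and 17. UTS2, OLFML3 and ITGB7 were high on days 5 and 13 and low on days 7 and 9. ITGB7, a leukocyte integrin, was at 12.27, 7.43, 7.72 and 11.70 in the order of the days, and at 11.97 in the authors' day 13 column. In limma MPO, ELANE, AZU1 and OAS1 fell on day 17 against the early arrays, and none of these 7 genes passed at day 9 or day 13 against the early arrays or between days 9 and 13, where UTS2, OLFML3 and ITGB7 had an adjusted p of 0.996. Day 5 was not tested against day 7.

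Of the tests of explanations below, the test for a small share of cells was written before its result was seen, and the others after. Genes bright on day 17 were often above the other arrays on day 9. Among 321 genes at least 16-fold higher on day 17 than the mean of the other arrays, day 9 was the highest of the other 4 in 64.5%, and days 5, 7 and 13 in 15.0%, 9.97% and 10.6%. Noise of dim probes that was independent between arrays would give 25 percent, so these shares argue against independent noise as the whole cause. They cannot tell apart a lift of all dim probes on day 9, which was not tested. Of the olfactory receptor probes, 5.30% were above background on day 9, against 4.42%, 4.64% and 3.75% on days 5, 7 and 13. A single small share of cells like those of day 17 may contribute: the median excess of the day 9 signal over the mean of days 5 and 13 was 0.861% of the day 17 signal (quartiles 0.284% and 1.74%), and 93.7% of the genes bright enough at that share, 118 of 126, were above background. That test is weak, because 71, 92 and 66 of the 126 were also above background on days 5, 7 and 13. It also passes over bright genes that were missing, since SULF1 and COL5A2 were not above background on day 9. Their day 9 signals were 3.19 and 22.3, where the median ratio of 0.796% given below predicted 210 and 151, with a background SD of 11.2. These 2 genes were thus far below a single share at that ratio. Carry-over of day 17 RNA at 1 ratio for all genes cannot be told apart from such a share: among the genes below background on days 5 and 13, 33.3%, 14 of 42 (95% binomial interval 19.6% to 49.5%), had a day 9 signal off their median ratio of 0.796%, 8 above and 6 below it, but 18 of the 42 were above background on day 7 and the cells of day 9 can express them too. Without those 18 it was 29.2%, 7 of 24 (12.6% to 51.1%), 5 above and 2 below their median ratio of 0.742%, so few genes keep carry-over open. Expression by the day 9 cells could only raise a signal, so it does not account for the genes below the ratio. Endothelial cells at another stage stay open as a hypothesis that was not tested.

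Erythroid, platelet and lymphocyte transcripts were higher on day 5 than later. Normalization between arrays is argued against for the erythroid list, because in the intensities as deposited it had a median of -3.29 on day 7 against day 5. The platelet and lymphocyte lists were not examined in that way. Remaining red cells, lymphocytes and platelets from the cord blood are a candidate source. At day 9 against day 5 the erythroid, B cell, T and NK cell and platelet lists had medians of -4.53, -2.38, -1.25 and -0.849. These medians are the flagged observation itself and no separate support for that source. Against day 7 alone the platelet list did not go on falling, with -1.54 on day 7 and -0.849 on day 9 relative to day 5. A difference in donor or culture between the days was not tested and stays open.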
